A study of Homo sapiens with 41 samples.

How the data were processed

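Bulk RNA sequencing was performed on 41 tumour libraries from 14 patients with soft tissue sarcoma treated before surgery with BO-112, a synthetic double-stranded RNA injected into the tumour, and hypofractionated radiation, with or without the PD-1 antibody nivolumab. Per the labels, total RNA was extracted from small cores of formalin-fixed, paraffin-embedded tissue and converted to libraries with a stranded total RNA kit for low inputs. The values deposited by the authors were TPM (transcript abundance scaled to a fixed library total) for 18952 protein-coding genes, and each column summed to 1000000. Per the submitters' processing notes, transcripts were quantified with Salmon and the genome build was GRCh38; versions and annotation were not given in the sources used here. TPM keeps no sequencing depth, so the depth per library is unknown and no counting interval was computed. The table held 47 columns of libraries, of which 41 matched a labelled sample by name; the other 6 columns were not used here.

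Libraries were grouped by the labelled time: T1 (baseline, n = 14), T2 (after 1 BO-112 dose, n = 8), T2b (after radiation and 1 BO-112 dose, n = 2), T3 (after radiation and 2 BO-112 doses, n = 6) and T4 (surgical resection, n = 11). Nivolumab had been given before 3 of the 6 T3 libraries and 6 of the 11 T4 libraries. Every patient had a T1 library, and T2, T2b, T3 and T4 could be paired with it in 8, 2, 6 and 11 patients. Because each patient was sampled repeatedly, the patient entered the model as a block. The pairing was checked on the deviations of libraries from their group means, whose median correlation was 0.481 between libraries of the same patient (42 pairs) and -0.021 between libraries of different patients (588 pairs). No pair of libraries held identical values, and the highest Pearson correlation of log2(TPM + 1) between any pair was 0.988. A check for mixed-up samples found 1 library that did not match the others of its patient, and it was kept. The check could not flag a mismatch in a patient with only 2 libraries, nor a swap between patients alike in what it compared. By correlation of expression centred per gene, the nearest library came from the same patient for 29 of 41 libraries.

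Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), that is with a pseudocount of 1, with patient and group as terms over all 41 libraries, which share one estimate of the spread, and with moderated, robust variances that follow the mean. Fold changes are on this scale, which understates changes of genes with low TPM. Genes needed a TPM of at least 1 in at least 6 libraries, and 45 Y-linked genes were left out beforehand, which left 18071 genes to test. P-values were adjusted by the method of Benjamini and Hochberg over the genes of each comparison, and an adjusted p below 0.05 was taken as a call. The effect of nivolumab was tested as the difference in change from T1 between patients with and without the antibody, with the T3 and T4 terms split, and the baseline libraries of the 7 patients who later received it were compared with the other 7 without a block. P-values of comparisons with the block rest on the spread of libraries within patients, pooled over all 41 libraries. Those of the baseline comparison rest on the spread between patients. Errors of fold changes are standard errors of the fit, and errors of TPM are SD.

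A set of 35 gene lists was fixed, covering immune cells and responses, tumour and radiation response, stroma, other tissue that a core can hold, and sample handling and RNA quality. A list score was the mean log2(TPM + 1) of its tested members, and scores were tested with the same limma model, adjusted over the 35 lists of a comparison. Of 502 list genes, 501 were found in the table and 498 were tested. CTLA4, CXCL9, CXCL10, CXCL11 and IDO1 stood in more than 1 list. Camera with a preset correlation of 0.01 and with an estimated correlation, fry, and a two-sided exact permutation test that flipped the signs of the patients' changes were run beside the score test. Members were also adjusted over the list alone.

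Genes were named by a rule: up to 8 genes with the largest and up to 8 with the smallest log2 fold change at T2, T3 or T4 against T1 among called genes with a mean TPM of at least 5 and the same direction in at least 75% of the patients with both libraries, up to 4 per direction in other comparisons, a fixed panel of 24 genes in every comparison, and up to 3 members with the smallest p of each called list. Grouping, design, lists, panel, naming rule and the following other settings were chosen before the data were examined: other pseudocounts (0.1 and 5), no filter or a TPM of at least 5, quantile and median-of-ratios scaling, rescaling without mitochondrial, haemoglobin and histone genes, no block or a random patient effect, pairs alone, array weights, the number of detected genes as a covariate, pooling of T2b with T2, patients with or without nivolumab alone, median scores, and leaving out each patient. Gene positions were taken from GENCODE release 29 on GRCh38, in which 18750 symbols were matched. Positions are 1-based.

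Library quality was described by the number of genes with a TPM of at least 1 and by the mean TPM of 375 olfactory receptor genes, which tissue outside the nose hardly transcribes. After the data were seen, 2 further settings were added: leaving out the 2 libraries that stand apart, and leaving them out with the log2 olfactory receptor mean as a covariate beside the patient block. All tests were two-sided, and Python 3.11.15 with pandas 2.3.3 prepared the tables. The procedure was tested on simulated data for 18071 genes made from the patients' means and the spread of each gene and library. Values were drawn independently between genes, which real genes are not, so the recovered shares may be optimistic. Of 50 genes changed by a log2 value of 2, 96% were recovered for T2 against T1, 74% for T3 and 94% for T4. At a log2 value of 1 these shares were 20%, 18% and 28%. Among the unchanged genes, 5, 19 and 1 were called, respectively.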

Results

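The data comprised TPM values of protein-coding genes in 41 libraries of soft tissue sarcomas from 14 patients. Baseline cores (T1) were available from all 14 patients, cores after 1 intratumoral dose of BO-112 (T2) from 8, cores after radiation of 5 fractions of 6 Gy with 1 BO-112 dose (T2b) from 2, cores after radiation with 2 BO-112 doses (T3) from 6, and resected tumour (T4) from 11. BO-112 is a double-stranded RNA mimic, which is sensed by TLR3, MDA5 (encoded by IFIH1) and related receptors. At T4, 5 patients had received 3 BO-112 doses without nivolumab, 2 had received 3 doses with 2 doses of nivolumab and 4 had received 2 doses with 1 dose of nivolumab.

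Between 10860 and 18093 genes per library had a TPM of at least 1, with means of 15107 ± 1751 (SD, n = 14) at T1, 14461 ± 2061 (n = 8) at T2, 15250 ± 1858 (n = 6) at T3 and 14096 ± 1300 (n = 11) at T4. Sequencing depth is unknown. The mean TPM of olfactory receptor genes, a measure of signal outside the tissue's own transcripts, had a median of 0.372 over all libraries and was 1.40 ± 1.82 (SD) at T1 and 0.599 ± 0.892 at T4. It reached 24.4 in 1 T2 library and 35.6 in 1 T3 library, whose mean Spearman correlations with the other libraries were 0.333 and 0.374. Lead values are therefore also given without these 2 libraries, an alternative chosen after seeing the data. Mitochondrially encoded genes made up 8.60% ± 4.15 of TPM at T1 and 9.41% ± 4.73 at T4.

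**Figure D1:**
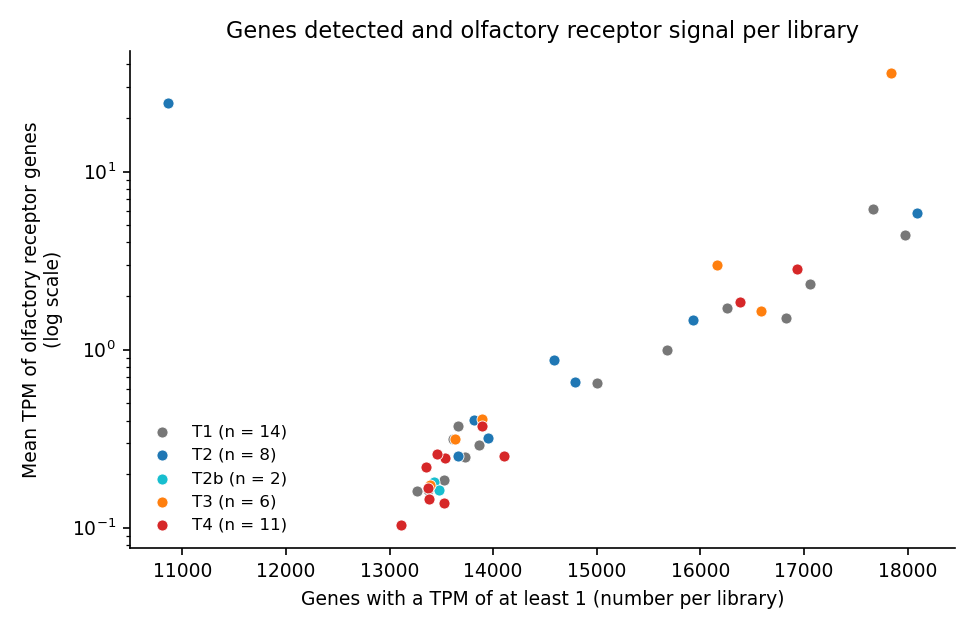
Number of genes with a TPM of at least 1 (x axis) against the mean TPM of 375 olfactory receptor genes (y axis, log scale), 1 point per library, coloured by time. The T2 library at 24.4 and the T3 library at 35.6 lie above all others, of which the highest is at 6.18.

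The comparison of T2 with T1 asked what differed in the tumour after a single injection of BO-112, before radiation. Per the labels, T2 and T3 were each sampled before the next BO-112 dose. The time since the last dose is not in the labels used here, so a response that had already passed would be missed. No gene was called between T2 and T1. In simulated data 20% of genes changed by a log2 value of 1 were recovered in this comparison, so changes of this size are not excluded. The antiviral genes ISG15, MX1 and IFIT1, which cells switch on in response to type I interferon, differed by -0.83 ± 0.73, 0.07 ± 0.54 and -0.44 ± 0.64 on the log2 scale (SE, 8 patients with both libraries). Their mean TPM was 55.0 ± 31.5 (SD), 126 ± 118 and 29.7 ± 29.9 at T1 and 50.7 ± 34.9, 103 ± 49.8 and 24.6 ± 15.5 at T2. The score of 25 type I interferon response genes differed by -0.32 ± 0.40 (adjusted p = 0.818, 95% interval -1.14 to 0.50), and it was higher at T2 in 4 of 8 patients, with changes from -2.80 to 1.35. Without the libraries that stand apart the difference was 0.08 (adjusted p = 0.993), with ISG15 at 0.19 and IFIT1 at 0.27.

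Other immune groups at T2 did not pass the test either. The 10 genes of double-stranded RNA sensing differed by -0.24 ± 0.23 and included IFIH1 (-0.67 ± 0.51) and TLR3 (0.15 ± 0.34). The 14 genes of the interferon gamma response differed by -0.29 ± 0.40, with changes from -3.18 in 1 patient to 1.73 and the T cell-attracting chemokines CXCL9 and CXCL10 at -0.23 ± 0.50 and 0.35 ± 0.76. Scores of T cells (0.16 ± 0.43), cytotoxic and NK cells (-0.33 ± 0.42) and B cells (0.60 ± 0.41) lay on both sides of baseline. MHC class I presentation genes differed by -0.46 ± 0.30 and inflammatory cytokines and NF-kB targets by 0.33 ± 0.29. With the 2 libraries left out, scores were 0.08 for the interferon gamma response, -0.02 for double-stranded RNA sensing, -0.06 for MHC class I, 0.08 for T cells, -0.22 for cytotoxic and NK cells and 0.26 for B cells (all adjusted p = 0.993). CXCL13, a B cell-attracting chemokine, was at -0.65 ± 0.71, the T cell gene CD3E at -0.22 ± 0.50, the B cell gene MS4A1 at 0.76 ± 0.72, and the checkpoint genes PDCD1 and LAG3 at 0.46 ± 0.50 and -0.64 ± 0.49. The macrophage genes CD68 and CD163 were at 0.10 ± 0.36 and -0.48 ± 0.38. CD8A, a marker of cytotoxic T cells, had a mean TPM of 11.6 ± 21.3 (SD) at T1 and 4.03 ± 3.73 at T2. For GZMB, which encodes a protease of killer cells, the means were 12.2 ± 21.2 and 3.31 ± 2.67. Those of CD274, which encodes PD-L1, were 14.0 ± 16.9 and 9.87 ± 8.83. These means are unpaired, over 14 and 8 libraries, and single T1 libraries reached 81.9 for CD8A and 82.5 for GZMB. Medians at T1 and T2 were 4.01 and 3.15 for CD8A, 4.85 and 2.70 for GZMB, and 9.22 and 7.34 for CD274. COL1A1, a collagen gene, differed by -0.87 ± 0.50 and the proliferation marker MKI67 by -0.85 ± 0.49, while TOP2A, a further proliferation gene, was at 0.33 ± 0.43. The endothelial gene PECAM1 (-0.19 ± 0.30) and the p53 targets CDKN1A (-0.41 ± 0.35) and MDM2 (-0.11 ± 0.28) did not pass the test. With the 2 libraries left out IFIH1 (0.07), MS4A1 (-0.19), PDCD1 (-0.03), CD163 (0.02) and MDM2 (0.08) lay on the other side of 0, COL1A1 was at -0.18 and MKI67 at -0.28. Extracellular matrix genes differed by -0.71 ± 0.34 (adjusted p = 0.818, lower in 7 of 8 patients), the lowest score over all 41 libraries. Leaving out the 2 libraries moved it to -0.28, above red blood cell (-1.18), mast cell (-0.51), skeletal muscle (-0.38) and endothelial genes (-0.30). With limma, 0 of 18071 genes had an adjusted p below 0.05, the smallest being 0.571, and 972 had an unadjusted p below 0.05, where 903.55 are expected by chance. Of the 35 lists, 0 were called by the score test, fry or camera with an estimated correlation and 8 by camera with a preset correlation.

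At T3, after radiation and a further dose of BO-112, CDKN1A, the cell cycle inhibitor induced by p53, had a mean TPM of 76.3 ± 39.8 (SD, n = 6) against 40.1 ± 22.6 (n = 14) at T1, a log2 difference of 1.01 ± 0.39 (SE) that was positive in 5 of 6 patients and did not pass the test (adjusted p = 0.938). MDM2, another p53 target, differed by 0.74 ± 0.31 in the same direction in 5 of 6 patients, and the score of 25 p53 target genes by 0.375 ± 0.196 (adjusted p = 0.574). Without the 2 libraries that stand apart CDKN1A was the only gene called, at 1.58 (adjusted p = 0.021); array weights over all 41 libraries also called it (1.72, adjusted p = 0.00356). In the smaller set the p53 score differed by 0.51 (adjusted p = 0.071). With the olfactory receptor signal also held constant the p53 score passed the test (adjusted p = 0.0396).

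Genes of connective tissue and vessels had low list scores at T3, none of which passed the test. Extracellular matrix and activated fibroblast genes differed by -1.04 ± 0.39 and were lower in all 6 patients (adjusted p = 0.420, exact permutation p = 0.0312 before and 0.547 after adjustment), with COL1A1 at -1.04 ± 0.56. Of the 20 members, 0 passed over all genes and 5 were lower when adjusted over the list alone. Without the libraries that stand apart this difference was -0.61 and 0 members were lower when adjusted over the list alone. Lower members then numbered 10 of 16 cytotoxic and NK cell, 7 of 14 endothelial and 4 of 9 smooth muscle and pericyte genes. Smooth muscle and pericyte genes (-0.67 ± 0.33) and endothelial genes (-0.65 ± 0.34) did not pass the test. The cytotoxic and NK cell score differed by -0.65 ± 0.48, and by -1.32 (adjusted p = 0.071) without the 2 libraries and -1.33 (adjusted p = 0.0396) with the olfactory receptor signal also held constant. Its members CD8A and GZMB differed by -0.9997 ± 0.68 and 0.61 ± 0.64, and the checkpoint gene LAG3 by -0.84 ± 0.55. The type I interferon score (0.10 ± 0.45), MX1 (0.68 ± 0.61), IFIT1 (0.51 ± 0.72) and ISG15 (-0.49 ± 0.82) did not pass the test. Nor did CXCL9 (-0.68 ± 0.56), CXCL10 (0.37 ± 0.86), CD274 (0.95 ± 0.46), or CD3E (-0.12 ± 0.56). The same held for CD68 (0.15 ± 0.40), CD163 (-0.33 ± 0.43), MKI67 (0.27 ± 0.55), TOP2A (0.650 ± 0.485) and PECAM1 (-0.48 ± 0.34). With limma, 0 genes were called at T3, 866 had an unadjusted p below 0.05 where 903.55 are expected, and 0 lists were called by the score test and 9 by camera with a preset correlation, of which none held with an estimated correlation.

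**Figure D2:**
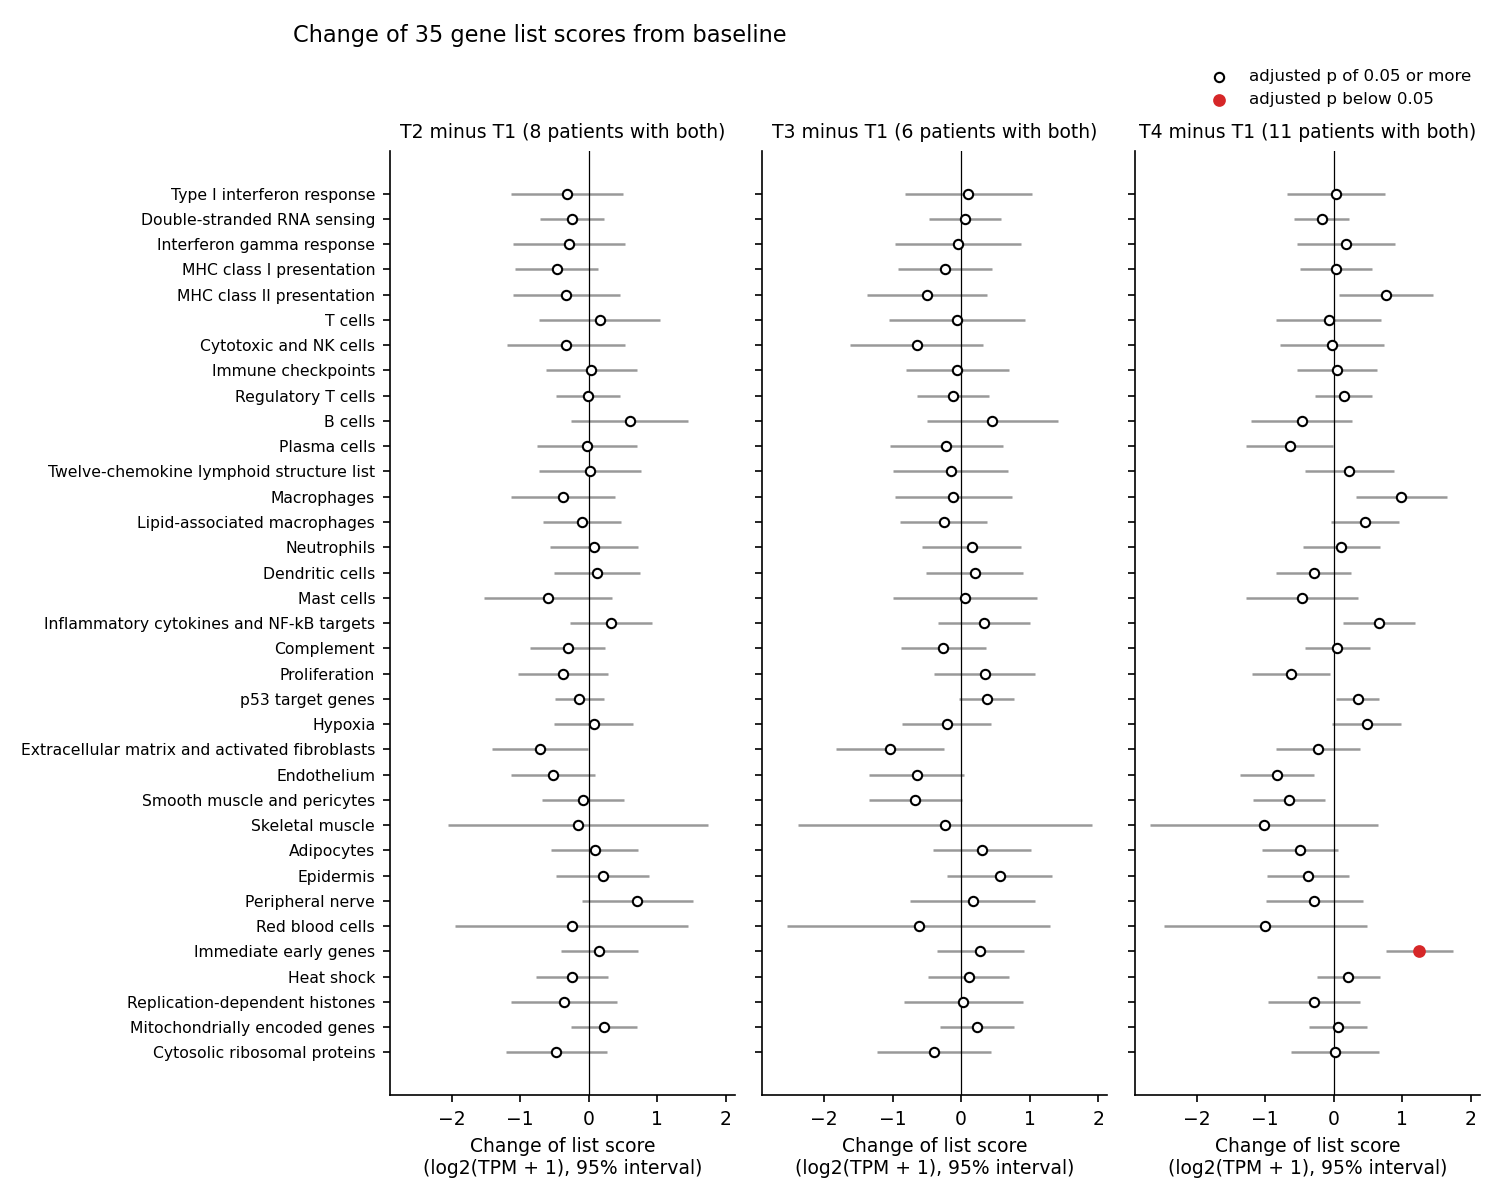
Change of 35 gene list scores from T1 to T2, T3 and T4, in log2(TPM + 1), as estimates of the joint model (points) with 95% intervals (lines); filled points mark an adjusted p below 0.05. The immediate early genes at T4, with a change of 1.25, are the only filled point.

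The resected tumours (T4) differed most from baseline, with 45 genes higher and 26 lower. The genes with the largest increases were RGS1, a regulator of G protein signalling in lymphocytes and myeloid cells (log2 difference 4.05 ± 0.59 SE, adjusted p = 0.000741), and the immediate early genes FOS (3.31 ± 0.47) and DUSP1 (2.93 ± 0.40), which cells transcribe within minutes of a stimulus. RGS1 had a mean TPM of 15.7 ± 13.9 (SD, n = 14) at T1 and 287 ± 298 (n = 11) at T4, FOS 21.1 ± 17 and 291 ± 252, and DUSP1 23.3 ± 10.8 and 215 ± 144. RGS1 and DUSP1 were higher in 11 of 11 patients and FOS in 10. They were followed by PTX3, a soluble pattern recognition protein (2.62 ± 0.42), TSC22D3, a glucocorticoid-induced gene (2.50 ± 0.36), RGS2 (2.38 ± 0.39) and PDK4, a kinase that restrains glucose oxidation (2.37 ± 0.46), each higher in at least 9 of 11 patients. The call of PTX3 ended without the patient block (adjusted p = 0.60) and with the block as a random effect (0.0578), and that of PDK4 without the block (0.138) and in the paired patients alone (0.0539). TSC22D3 had a mean TPM of 139 ± 64.0 (SD) at T1 and 860 ± 476 at T4.

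The list of 13 immediate early genes was the only 1 of 35 called, with a score higher by 1.25 ± 0.24 (adjusted p = 0.000533) and in 10 of 11 patients. Of its members 4 rose, FOS, FOSB, DUSP1 and KLF6 (1.12 ± 0.21), and 8 rose when adjusted over the list alone. The call of KLF6 ended without the patient block (adjusted p = 0.0688), with the number of detected genes held constant (0.0614) and in 1 of the 14 fits that left out 1 patient (0.0550). The call of the list held with an estimated correlation (adjusted p = 0.000568), and without the 2 libraries that stand apart the score was higher by 1.27. In the list of 14 macrophage genes 2 members rose over all genes, the scavenger receptor CD163 (1.60 ± 0.33, adjusted p = 0.024, 11 of 11 patients) and VSIG4, a complement receptor of tissue macrophages, and 10 rose when adjusted over the list alone. Mean TPM of CD163 was 213 ± 145 (SD) at T1 and 640 ± 499 at T4. The call of CD163 ended without the patient block (adjusted p = 0.540) and with the block as a random effect (0.067). It also ended with T2b pooled with T2 (0.056), with the number of detected genes held constant (0.0533) and in 8 of the 14 fits that left out 1 patient (up to 0.125). The macrophage score differed by 0.99 ± 0.32 and was higher in 11 of 11 patients (adjusted p = 0.0584 by limma, exact permutation p = 0.000977 before and 0.0342 after adjustment); without the 2 libraries it was higher by 1.06 (adjusted p = 0.000601). It also passed with a pseudocount of 5 (0.0322), a TPM of at least 5 (0.0453), quantile (0.0373) and median-of-ratios scaling (0.0399), the number of detected genes held constant (0.0342), the paired patients alone (0.0273) and the median over members (0.0425). The macrophage score passed without the patient whose T2 library stands apart (0.00111) and without another patient (0.0220). It did not pass in the other fits that left out 1 patient, without the patient block, with the block as a random effect or with a pseudocount of 0.1. Lipid-associated macrophage genes differed by 0.46 ± 0.24 (adjusted p = 0.221) and were higher with the number of detected genes held constant (0.74, adjusted p = 0.0342) and, without the 2 libraries, with the olfactory receptor signal held constant (0.79, adjusted p = 0.00701).

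Of the p53 targets, MDM2 rose at T4 by 1.14 ± 0.24 (adjusted p = 0.0327, 11 of 11 patients); CDKN1A differed by 1.05 ± 0.30 and was higher in 10 of 11 patients without passing the test (adjusted p = 0.139, and 0.00152 without the 2 libraries). Mean TPM of MDM2 was 668 ± 1037 (SD) at T1 and 1643 ± 2222 at T4. Medians were 207 and 566, and single libraries reached 3519 and 7173. Why MDM2 was so high in single libraries was not tested, so its rise alone cannot be read as p53 activity. For MDM2 the call ended without the patient block (adjusted p = 0.849) and with the block as a random effect (0.337). The same held with T2b pooled with T2 (0.0967), with the number of detected genes held constant (0.221) and in 8 of the 14 fits that left out 1 patient (up to 0.147). The p53 target score differed by 0.35 ± 0.15 (adjusted p = 0.145, 0.036 without the 2 libraries, 0.0265 with quantile and 0.0430 with median-of-ratios scaling), with 1 of its 25 members called over all genes and 4 when adjusted over the list alone. The score of 19 inflammatory cytokines and NF-kB targets differed by 0.661 ± 0.255 (adjusted p = 0.116, and 0.036 without the 2 libraries), with NFKBIZ as its called member. It passed over all libraries with a pseudocount of 5 (0.0346), a TPM of at least 5 (0.0449), quantile scaling (0.961, adjusted p = 0.00217), median-of-ratios scaling (0.0399) and the number of detected genes held constant (0.0293). The score of the 10 MHC class II genes differed by 0.76 ± 0.33 (adjusted p = 0.145, and 0.0195 without the 2 libraries). Type I interferon genes (0.03 ± 0.35), T cells (-0.07 ± 0.38), cytotoxic and NK cells (-0.03 ± 0.37) and immune checkpoints (0.05 ± 0.28) did not pass the test. With the olfactory receptor signal held constant and the 2 libraries left out, differences were 0.41 for T cells, 0.42 for cytotoxic and NK cells and 0.54 for immune checkpoints (adjusted p = 0.309, 0.319 and 0.0804). CD274 (-0.24 ± 0.36), PDCD1, which encodes PD-1 (0.04 ± 0.43), CD8A (0.09 ± 0.53) and CXCL9 (0.47 ± 0.43) did not pass the test.

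Among the genes lower at T4 were BCL6B (-1.81 ± 0.36) and TIE1 (-1.66 ± 0.35), both known from endothelial cells, TSPAN18 (-1.49 ± 0.32), the lipase gene LIPE (-1.62 ± 0.34), CPT1C (-1.49 ± 0.34), HOXA6 (-1.72 ± 0.39), FFAR2, a receptor for short-chain fatty acids (-1.96 ± 0.43), and the transcript L34079.2 (-2.03 ± 0.45). BCL6B, TIE1, TSPAN18, CPT1C and HOXA6 were lower in all 11 patients, L34079.2 and LIPE in 10 and FFAR2 in 9. Mean TPM of TIE1 was 31.1 ± 37.1 (SD) at T1 and 7.91 ± 8.38 at T4, and that of BCL6B 32.9 ± 21.7 and 10.5 ± 10.7. The endothelial score differed by -0.83 ± 0.26 (adjusted p = 0.0584, lower in 9 of 11 patients) and by -0.76 without the 2 libraries (adjusted p = 0.0195), and it passed with a pseudocount of 5 (0.0322), a TPM of at least 5 (0.0449) and the median over members (0.0425); 1 of its 14 members was lower over all genes and 7 when adjusted over the list alone. PECAM1, a further endothelial gene, was at -0.11 ± 0.26. With the olfactory receptor signal held constant and without the 2 libraries, BCL6B, TSPAN18 and LIPE kept their calls, while TIE1 was at -1.19 (adjusted p = 0.0684) and CPT1C at -0.87 (adjusted p = 0.0732). HOXA6 was at -1.17 (adjusted p = 0.12), FFAR2 at -1.13 (adjusted p = 0.0769), L34079.2 at -1.42 (adjusted p = 0.0541), and the endothelial score at -0.63 (adjusted p = 0.0791). With the number of detected genes held constant over all 41 libraries, none of these 8 genes kept its call (BCL6B -1.37, adjusted p = 0.142; TSPAN18 -1.51, 0.0858; LIPE -1.04, 0.171; TIE1 -1.21, 0.209; the others up to 0.288 for CPT1C). Without the patient block none did either (adjusted p = 0.322 for BCL6B to 0.849 for LIPE, CPT1C and FFAR2). Leaving out 1 patient ended the call of BCL6B in 2 of 14 fits and of the others in 7 to 11. COL1A1 did not pass over all libraries (-1.11 ± 0.44, adjusted p = 0.292) and was lower without the 2 libraries (-1.08, adjusted p = 0.00534), with the olfactory receptor signal also held constant (0.0245), in the paired patients alone (0.0489) and with array weights (0.0105). The proliferation score (-0.62 ± 0.28, adjusted p = 0.145) and MKI67 (-0.69 ± 0.43) did not pass the test.

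The numbers of genes at T4 moved with the libraries included and the scale. Without the 2 libraries 351 genes were higher and 850 lower, with all 71 calls shared. With the olfactory receptor signal also held constant 202 were higher and 108 lower. Neither of the 2 libraries is from T1 or T4, so they enter this comparison through the shared spread and the patient terms. The counts over all 41 libraries therefore also depend on libraries outside the comparison. In the paired patients alone 34.9% of called genes were higher, against 63.4% over all libraries. The median change of all genes was -0.27; quantile scaling, which brought it to -0.00, gave 53 higher and 6 lower, and median-of-ratios scaling, with a median of -0.15, gave 81 and 18. Without the patient block 7 genes were higher and 1 lower. With the number of detected genes held constant 30 were higher and 3 lower, and 21 of the 45 higher and 2 of the 26 lower genes kept their call. Leaving out each patient in turn gave 17 to 149 higher and 3 to 227 lower, the highest of both without the patient whose T2 library stands apart.

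**Figure D3:**
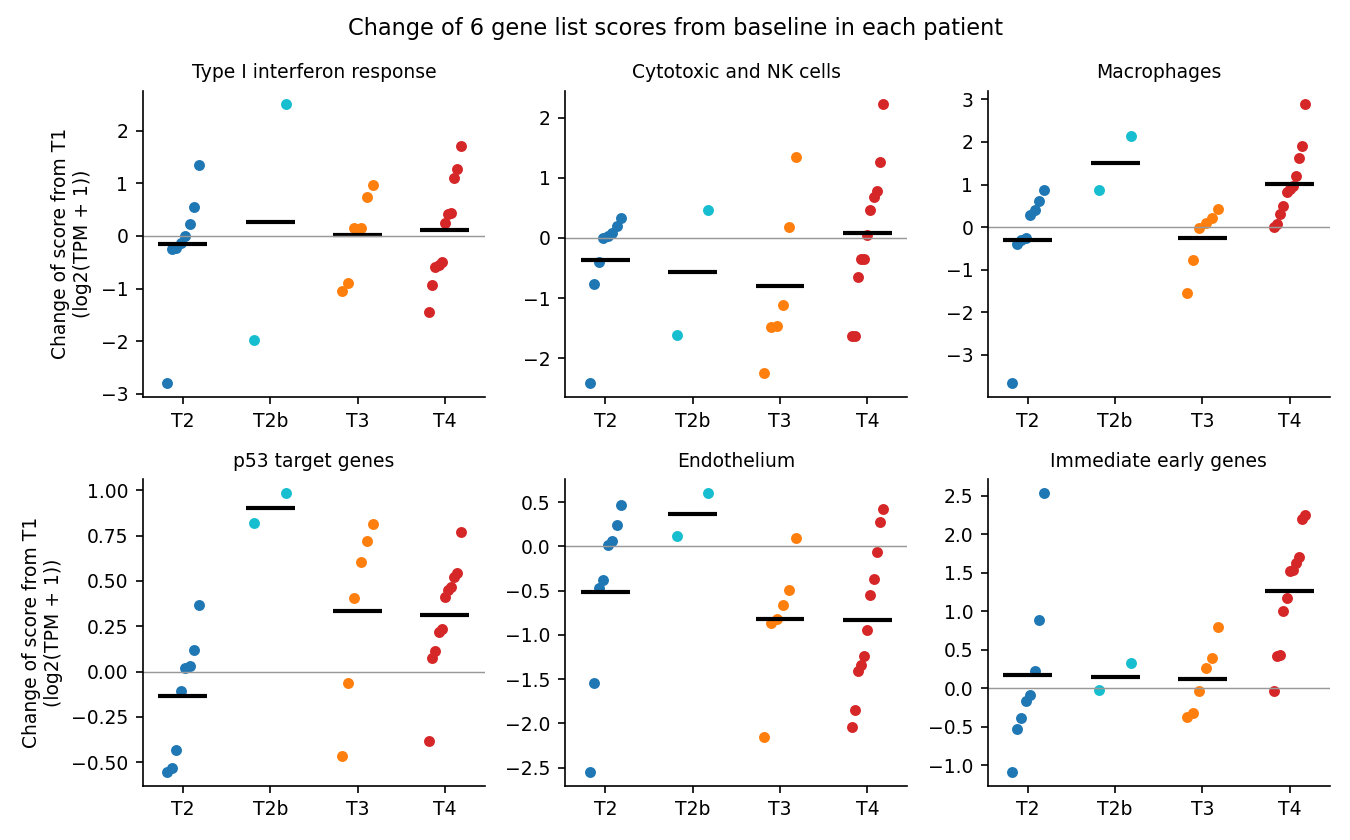
Change of 6 gene list scores from T1 in each patient, in log2(TPM + 1); points are patients with both libraries (8 at T2, 2 at T2b, 6 at T3 and 11 at T4) and horizontal lines their means. The macrophage score at T4 lies above 0 in all 11 patients, and the type I interferon score at T2 in 4 of 8.

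In the genome (GRCh38), RGS1 lies on chromosome 1 from 192575727 to 192580031, FOS on chromosome 14 from 75278774 to 75282230, DUSP1 on chromosome 5 from 172768090 to 172771195, CD163 on chromosome 12 from 7470813 to 7503893, MDM2 on chromosome 12 from 68808176 to 68850686, and TIE1 on chromosome 1 from 43300993 to 43323108. TPM sums over all transcripts of each gene.

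**Figure D4:**
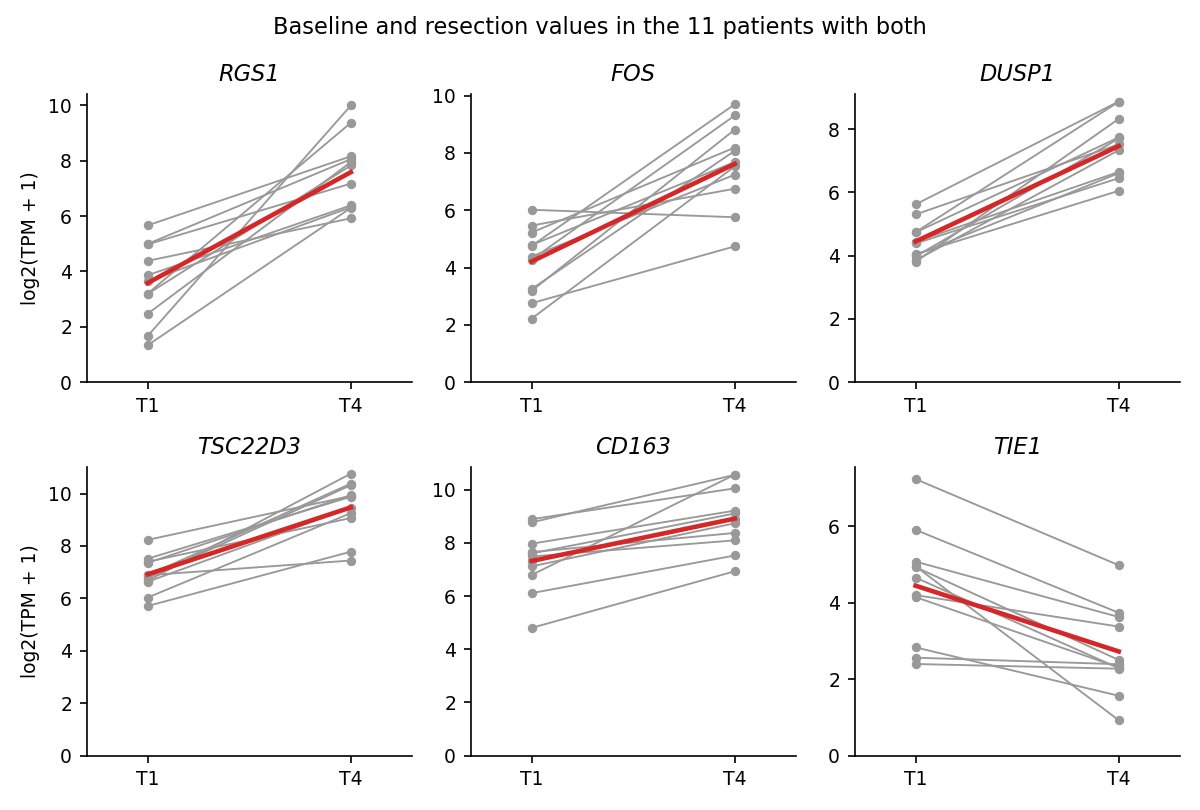
log2(TPM + 1) of 6 genes at T1 and T4 in the 11 patients with both libraries (grey lines, 1 per patient) and their mean (red line). RGS1, DUSP1, TSC22D3 and CD163 are higher at T4 in all 11 patients, FOS in 10, and TIE1 is lower in all 11.

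Between T3 and T4, which both follow radiation, 4 genes were higher and 1 lower at T4. The stress-inducible genes C10orf10 (2.71 ± 0.41, adjusted p = 0.00642), DDIT4, an inhibitor of mTOR signalling (2.31 ± 0.38), and MT2A, a metallothionein (2.29 ± 0.43), were higher, and FFAR2 was lower (-3.29 ± 0.62), each in the same direction in the 3 patients with both libraries. RGS1 was the remaining gene (4.52 ± 0.84, higher in 2 of 3 patients); it was named after its values were seen. In the paired patients alone 0 genes were called (adjusted p = 0.542 for the first 4). With the number of detected genes held constant the calls of DDIT4 (0.129), MT2A (0.140) and FFAR2 (0.157) ended. Those of MT2A and FFAR2 ended without the patient block (0.330 and 0.360), with the block as a random effect (0.117 and 0.159) and with a pseudocount of 0.1 (0.0728 and 0.0828). The call of MT2A also ended with quantile scaling (0.0509), with T2b pooled with T2 (0.0536) and on the scale without mitochondrial, haemoglobin and histone genes (0.0579). Of the 14 fits that left out 1 patient, 1 ended the call of C10orf10, 2 that of DDIT4, 7 that of MT2A and 10 that of FFAR2. CD163 differed by 1.93 ± 0.47 (adjusted p = 0.113) and was higher without the 2 libraries (1.83, adjusted p = 0.0133), with the olfactory receptor signal also held constant (0.0336), with array weights (0.00172) and without the patient whose T2 library stands apart (0.0025). The immediate early score differed by 0.97 ± 0.34 (adjusted p = 0.202). The median change of all genes was -0.38. Without the 2 libraries 46 genes were called, and FFAR2 was at -2.63 (adjusted p = 0.0564); with the olfactory receptor signal also held constant 77 were. Leaving out each patient in turn gave 0 to 325 called genes, the highest without the patient whose T2 library stands apart.

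Between T2 and T3, CDKN1A differed by 1.42 ± 0.41 and MDM2 by 0.85 ± 0.33 on the log2 scale (both adjusted p = 0.641), and the p53 target score by 0.51 ± 0.21 (adjusted p = 0.732). With limma 0 genes were called and 1339 had an unadjusted p below 0.05, where 903.55 are expected by chance. Without the 2 libraries CDKN1A was the only gene called, at 1.64 (adjusted p = 0.0359), and array weights also called it (1.80, adjusted p = 0.00142).

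The 2 patients sampled after radiation with 1 BO-112 dose (T2b) gave values for p53 targets above their baselines. At the main setting over all 41 libraries these values did not pass the limma test. CDKN1A differed by 2.09 ± 0.65, MDM2 by 2.01 ± 0.52 and CD163 by 1.85 ± 0.71, each higher in both patients, and the p53 target score by 0.83 ± 0.33 (adjusted p = 0.580, 0.084 without the 2 libraries that stand apart, and 0.0376, at 0.87, with the olfactory receptor signal also held constant). Against T2, which followed the same number of BO-112 doses without radiation, the p53 score differed by 0.97 ± 0.36 (adjusted p = 0.408). No patient had both, so changes from T1 in 2 patients were set against those in 8 others. Radiation cannot be told apart from differences between these patients. With limma 0 genes were called in either comparison, and 85 and 140 had an unadjusted p below 0.05, where 903.55 are expected by chance. Without the 2 libraries these numbers were 365 and 302. P-values thus ran high in these comparisons, and the lack of calls says little about absence of change. Array weights called CDKN1A (2.07, adjusted p = 0.00413), MDM2 (1.66, 0.0161) and CD163 (1.91, 0.0161) against T1, and CDKN1A (2.14, 0.00807) and MDM2 (1.69, 0.0330) against T2. Camera with an estimated correlation called p53 targets against T1 (adjusted p = 0.0000540) and T2 (0.00406) and macrophages against T1 (0.0224), and fry called p53 targets against T2 (0.0283). TPM of MDM2 was 458 in 1 T2b library and 9437 in the other, so its level differed widely between these tumours. With 2 libraries, the spread of this group was taken from the other groups.

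Patients with and without nivolumab were compared by their changes from T1. At T4, 6 against 5 patients, the changes of the panel genes differed by -0.82 to 0.61, with CD8A and CD274 among them; PDCD1 differed by -0.72 ± 0.78 and GZMB by -0.59 ± 0.87. No gene was called with limma, and 0 of 35 lists passed (smallest adjusted p = 0.433). An unadjusted p below 0.05 was found for 278 genes, where 903.55 are expected by chance, and for 745 without the 2 libraries that stand apart. P-values thus ran high here too, and the lack of calls says little about absence of an effect. Of the 6 patients given nivolumab 4 had received 2 instead of 3 BO-112 doses. Among the libraries with 3 doses, 2 with and 5 without nivolumab, 0 genes were called and 169 had an unadjusted p below 0.05.

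At T3, 3 against 3 patients, the changes differed by 2.70 ± 0.94 for CD3E, a T cell receptor gene, 2.70 ± 1.09 for GZMB, -1.93 ± 0.65 for CDKN1A and -3.32 ± 1.43 for ISG15 (adjusted p = 0.239 to 0.247), and by 2.03 ± 0.97 for PDCD1 (adjusted p = 0.267). No gene was called and 3315 had an unadjusted p below 0.05, where 903.55 are expected by chance. Leaving out the 2 libraries, 1 of which belongs to a patient given nivolumab, moved these values to 2.24, 2.13, -0.78, -0.71 and 1.44 (adjusted p = 0.945 to 0.968), with 854 genes below 0.05. PDCD1 was called with array weights (3.02, adjusted p = 0.0369). Leaving out each patient in turn gave 0 to 1256 called genes, with PDCD1 (3.47, adjusted p = 0.0418) and CDKN1A (-2.68, 0.0379) called in 1 of the fits. The smallest exact permutation p with 3 against 3 patients is 0.1, and none of the 35 lists passed the limma test (smallest adjusted p = 0.256).

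Before any treatment, tumours of the 7 patients later given nivolumab differed from the other 7 by -2.02 ± 0.72 in CD3E, -1.93 ± 0.69 in CD8A and -1.38 ± 0.71 in GZMB, and by -1.39 ± 0.60 in the cytotoxic and NK cell score (adjusted p = 0.388). With limma 0 genes were called and 647 had an unadjusted p below 0.05, where 903.55 are expected by chance.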

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

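The test on genes of 4 silent families was written before its result but after the olfactory receptor values had been seen; the splits of the libraries and the tests of mislabelling, background, specimen handling and treatment were chosen after the results they address. Libraries or changes were marked where 1 value lay far from the others of its time by Dixon's ratio; 82 sets were examined, 20 were marked, and chance alone marks about 4.1.

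In the T2 library that stands apart the olfactory receptor genes had a mean TPM of 24.4 (others 0.251 to 5.86) and the mean Spearman correlation with other libraries was 0.333; in the T3 library these values were 35.6 and 0.374. The median TPM of the latter was 28.5, above all other T3 libraries; among T2 libraries the median TPM that lay apart, 20.8, was that of another library. Changes from T1 to T2 that lay below all others were -2.80 for type I interferon genes, -1.78 for double-stranded RNA sensing, -3.18 for the interferon gamma response, -3.09 for MHC class I, -3.34 for MHC class II, -2.42 for cytotoxic and NK cells, -3.67 for macrophages, -2.86 for extracellular matrix, -2.12 for heat shock and -3.40 for cytosolic ribosomal proteins. Changes from T1 to T3 that lay below all others were -3.95 for mast cells, -3.75 for extracellular matrix, -1.21 for heat shock and -2.93 for cytosolic ribosomal proteins. The changes at T3 and T4 differed, by the test of T4 against T3, for C10orf10 (2.71), DDIT4 (2.31), FFAR2 (-3.29), MT2A (2.29) and RGS1 (4.52).

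The 2 libraries that stand apart were weighed first. Their highest Spearman correlation with any library was 0.526, while each of the other 39 libraries had a partner at 0.867 or more. Libraries made up mostly of background would correlate poorly with all others, whether swapped or not. These values therefore cannot decide whether these 2 libraries were mislabelled or swapped. For reads spread over the genome, such as DNA or unspliced RNA, 152 genes of keratin-associated proteins, beta-defensins and taste and vomeronasal receptors, which soft tissue hardly uses, had a mean TPM of 18.9 and 21.8 in them, 27.5 times the median of the others in the lower of both. The 2 libraries differed in other respects. The T2 library had the fewest genes with a TPM of at least 1 (10860), the most at 0 (7693) and the lowest median TPM (6.37). In the T3 library these values were 17842, 1008 and 28.5. Background of this kind may account for their distance from the other libraries. Whether the few genes detected in the T2 library have a further cause was not tested. No biological explanation was tested.

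The rise of immediate early genes at T4 was not removed by the lower background of the T4 libraries: with the olfactory receptor signal held constant and without the 2 libraries the score was still higher by 1.31 (adjusted p = 0.00136), and with the number of detected genes held constant by 1.38. Handling of the resected specimen, with time without blood supply before fixation, could give the difference of 0.97 between T4 and T3, but every T4 library and no other came from a resection. The combined treatment could also contribute; the score at T3, also after radiation, differed from T1 by 0.28 with an interval of -0.35 to 0.91. Handling and treatment cannot be told apart in this design.

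The excess of lower genes at T4 may in part follow the fall in background. Without the 2 libraries 70.8% of called genes were lower, and with the olfactory receptor signal held constant 34.8% were. Of the 26 lower genes called over all 41 libraries 17 kept their call with this covariate, at a median change of -1.09 without it (median SE 0.219) and -0.997 with it (0.232), while the median of all genes moved from -0.24 to -0.04. With the number of detected genes held constant instead, 2 kept their call, at a median of -1.12 without (0.240) and -0.958 with it (0.255), while the median of all genes moved from -0.27 to -0.05. Calls over all genes then fell from 71 to 33, and why those of the other 24 ended was not shown. Most of the size was left with either covariate, but the 26 genes had been chosen for being lower in these same libraries. Either covariate may also capture only part of the background. These fits therefore cannot decide whether background was the whole cause or a share of it. Loss of vessels after treatment stays open and was not tested.

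To see how many genes other splits give, time labels were swapped within patients, and for the nivolumab and baseline comparisons patients were reassigned between the arms. For T4 against T1, 1 of 100 splits, the real one with 71 genes, gave as many, and the highest other gave 2, so chance was excluded at this level. Where the real count was 0 every split reaches it, so the splits say nothing about chance. This holds for T2 against T1 (100 of 100 splits, highest other 0), T3 against T1 (64 of 64, highest other 1), T3 against T2 (32 of 32, highest other 692), and for nivolumab at T4 (100 of 100, highest other 0) and baseline (100 of 100, highest other 7). The 692 genes came from 1 of the 16 splits that put both libraries that stand apart into the same group, and the other 15 and the 16 further splits gave 0. A count this high points to some structure of the samples, whose cause was not shown. The splits were too few for T4 against T3 (2 of 8 gave at least 5 genes; highest other 5) and for nivolumab at T3 (10 of 10; real count 0, highest other 0).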

How the results depend on the processing

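No named gene or list called over all 41 libraries changed its sign at another setting. The balance at T4 against T1 did turn, from 63.4% of called genes higher to 29.2% without the 2 libraries that stand apart, 37.6% with array weights, 34.9% in pairs alone with the block and 39.6% without the patient whose T2 library stands apart. Further, 822 values of genes and lists that passed no test changed sign among 10940 comparisons with the main setting. The settings without the 2 libraries that stand apart were chosen after seeing the data; all others were planned. TPM keeps no depth, so the effect of depth was not examined, and where no construction shows it the cause was not tested. For T4 against T1 (45 genes higher, 26 lower, 1 list), a TPM of at least 5 gave 41 lower and 4 lists, a pseudocount of 5 gave 4 lists, quantile scaling gave 6 lower and 4 lists, median-of-ratios scaling gave 81 higher and 4 lists, and the detected-gene covariate with the patient block gave 3 lower and 4 lists. Without the patient block 7 genes were higher and 1 lower, and with the block as a random effect 25 and 6. Array weights gave 630 higher and 1044 lower, and the paired patients alone, with the block and fewer samples, 119 higher, 222 lower and 2 lists. Patients given nivolumab alone gave 6 higher and 0 lower, and the others alone 0 higher, 0 lower and 0 lists, with fewer samples. The set without the 2 libraries gave 351 higher and 850 lower, with 6 lists, and with the olfactory covariate and the block 202, 108 and 6 lists. Median scores gave 4 lists, camera 21 with a preset and 4 with an estimated correlation, and fry 5. For T3 against T1 (0 genes and 0 lists), array weights gave 2 higher, patients given nivolumab alone 1 lower, the set without the 2 libraries 1 higher, the olfactory covariate with the block 1 higher and 2 lists, and camera with a preset correlation 9 lists; for T2 against T1 the last gave 8. For T4 against T3 (5 genes), a pseudocount of 0.1 gave 2, of 5 gave 20, a TPM of at least 5 gave 8, quantile scaling 8, median-of-ratios scaling 19, the random block 8, array weights 347, the detected-gene covariate with the block 2, pairs alone with the block 0, the set without the 2 libraries 46 and the olfactory covariate with the block 77. For T3 against T2 (0), array weights gave 6 and the set without the 2 libraries 1. Array weights gave 6 genes for T2b against T1, 3 for T2b against T2 and 220 for nivolumab at T3, where quantile scaling gave 1. Leaving out each patient in turn gave ranges of 17 to 149 higher, 3 to 227 lower and 1 to 7 lists for T4 against T1, 0 to 1 lower for T3 against T1, 0 to 1 for T3 against T2, 0 to 325 for T4 against T3 and 0 to 1256 for nivolumab at T3. The restriction to libraries with 3 BO-112 doses kept 0 calls for nivolumab at T4.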

Other observations

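The settings without the 2 libraries that stand apart were chosen after the data were seen, and the hypothesis on glucocorticoids came from the genes called at T4. The macrophage and MHC class II scores were higher in the resections than in the irradiated biopsies (T3) once these 2 libraries were left out, by 1.14 and 1.31 (both adjusted p = 0.0351). Among the other immune cell scores, those of cytotoxic and NK cells (1.41, adjusted p = 0.0502) and T cells (0.86, adjusted p = 0.271) did not pass the test. With the olfactory receptor signal also held constant the cytotoxic and NK cell score differed by 1.75 (adjusted p = 0.0217), lipid-associated macrophages by 0.98 and immune checkpoints by 1.05 (both adjusted p = 0.0224), and T cells by 1.26 (adjusted p = 0.032). In this set 2 patients had both libraries, and none of these 6 scores was called over all 41 libraries.

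Several of the genes raised at T4, among them TSC22D3, DDIT4, MT2A, SGK1, GLUL and DUSP1, are known to be induced by glucocorticoids. The hypothesis of exposure to glucocorticoids around surgery was tested on 10 other such genes, none of them called at T4 and none in the fixed lists (FKBP5, PER1, ZBTB16, KLF9, ERRFI1, MT1X, MT1M, IL1R2, CRISPLD2 and KLF15). The set was written after the 71 genes called at T4 had been seen and was chosen so that none of these 10 was among them; their values were not looked at before the prediction was written, and no other set was tried. Their mean log2(TPM + 1) was higher at T4 than at T1 by 1.05 ± 0.23 (SE, 95% interval 0.57 to 1.52) and in 11 of 11 patients (two-sided exact permutation p = 0.000977, the smallest it can give). FKBP5 differed by 1.25, PER1 by 1.54 and ZBTB16 by 1.62, while IL1R2 (0.28), CRISPLD2 (0.17) and KLF15 (0.32) differed by less than their errors. None of 10000 random lists of 10 genes matched on expression reached as high a mean. Their members were drawn independently, so any set of genes that rise together at T4 could exceed them, whatever the cause. The same genes differed from T1 by -0.43 ± 0.26 at T2 and 0.08 ± 0.30 at T3, and between T4 and T3 by 0.97 (95% interval 0.30 to 1.64). Without the 2 libraries and with the olfactory receptor signal held constant the T4 difference was 1.28. Glucocorticoids given or released around surgery are thus a candidate explanation for part of the T4 changes; some of these genes also respond to other stress, and medication was not analysed here.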
